A study of Mus musculus with 36 samples.

How the data were processed

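Small RNA libraries of 4 brain regions (cerebellum, cortex, midbrain and brain stem) from 9 mice were analysed, with 36 libraries in all. Per the labels' protocols, libraries were prepared with the TruSeq small RNA kit from size-selected short inserts, and the mice were 42 to 45 days old. Groups were taken from the labels: WT, 4L;C* and IFG-treated 4L;C*, with 3 mice each, except that 1 WT brain stem library was labelled only as an outlier and was left unassigned, so that WT brain stem had 2 libraries. Column titles call the treated group high, and this was read as the isofagomine group because the labels give no other treated group. Library names carry mouse numbers, and these were used to match the regions of a mouse. All libraries carried 1 run and 1 lane in their names, so no sequencing batch could be compared.

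The values deposited by the authors are on a log2 scale. Per the file, each feature had a median of 0 over the 36 libraries, so levels were relative between features. Reads were aligned to mouse build mm 9 per the submitters' processing notes, and the aligner, the counting method and the normalization tool are not given in the sources used here. The spacing of the low values of each library showed that a deposited value was the log2 of whole reads multiplied by 1 factor per library, floored at 1 scaled read, minus the median of the feature. This was tested on features whose level was recovered, without 2868 features at 1 value and 28 not recovered: 99.8% of 125176 values above the floor lay within 0.05 reads of a whole number. For 1488 features never at the floor the level was itself solved to give whole reads, in a search of up to 300000 reads, so the test is weaker there. Over grouped libraries 1 read was worth from 0.595 to 1.88 scaled reads. The factors followed a median of ratios over the 1488 features seen in every library of all small RNA classes (r = 0.9956 across libraries) more closely than over mature miRNAs alone (430 features, r = 0.9658). The authors also deposited group averages, and their WT brain stem average includes the library labelled outlier: 3978 features differed, by up to 2.5, from the average of the other 2, and 0 differed with it.

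The deposited table held 8654 features: 1277 mature miRNA, 736 miRNA precursor, 1476 snoRNA or scaRNA, 1453 U RNA, 433 tRNA, 46 other small RNA and 3233 unannotated regions. Mature miRNAs were tested, 1 feature per name (the locus with the highest mean), where above the floor in at least 18 of the 35 grouped libraries, which left 614 of 1148 names, of which 838 had any signal. The choice of 1 feature per name was made after the structure of the table was seen and before any test. For 10 highly abundant names the read level could not be recovered, and they were tested on the deposited scale and left out of read totals. Their absence lowers the stated depth. Chromosomes and end coordinates are those of the files. Recovered mature reads ranged from 688475 to 3045139 per grouped library, the 10 most abundant miRNAs took 38.3% to 52.9% of them, and 1.79% to 9.61% of the tested miRNAs lay at the floor.

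Comparisons used limma 3.58.1 in R 4.3.3 with trend and robust settings on the deposited log2 values. All 35 grouped libraries entered a model of 12 groups, from which 4L;C* was compared with WT, IFG-treated with untreated 4L;C*, and IFG-treated 4L;C* with WT in each region. The spread of the WT brain stem group of 2 thus drew on all groups. The same 3 comparisons were made on means per mouse over cerebellum, cortex and midbrain. In WT, each region was compared with the mean of the others over 11 libraries. Moderated F tests asked whether the genotype or the treatment effect differed between regions. P values were two-sided and adjusted by Benjamini-Hochberg over the 614 miRNAs, with a threshold of 0.05. WT serves in both comparisons with WT, and untreated 4L;C* in both comparisons with it, so these are not independent. In named comparisons the rule asked for groups that do not overlap, which chance gives for 10% of features with 3 against 3.

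There were 25 miRNA lists fixed before the data were examined: neuron-enriched, activity-regulated, microglia and haematopoietic, inflammation-responsive, oligodendrocyte, astrocyte-associated, vascular, erythroid, choroid plexus and ciliated epithelium, Hox-cluster hindbrain, cerebellum-associated, forebrain-associated, Dlk1-Dio3 imprinted cluster, let-7 family, miR-17-92 and paralogues, miR-29 family, miR-30 family, miR-34 family, miR-181 family, miR-183 cluster, alpha-synuclein and Parkinson-associated, glucocerebrosidase-associated, autophagy and lysosome, cholesterol and lipid, and muscle. Some miRNAs are in several lists. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison. Named miRNAs followed a rule, also set before the data were examined, as were the comparisons, tests and the main alternatives: among miRNAs that passed with groups that did not overlap, the 12 largest rises and 12 largest falls (8 each for regions), not among the lowest 25% by mean level, and up to 4 members per list with the smallest p. The miRNAs named for effects that differ between regions, those shared by several regions, and a few list members given without full statistics were chosen after their values were seen.

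Reversal of the genotype effect was measured by the correlation across miRNAs of the 2 changes, set against 1000 simulated draws of unchanged groups that share the untreated libraries. The alternatives were no filter, a stricter filter, quantile normalization, centring of each library on its median tested miRNA, limma without trend and robust settings, the 2 compared groups alone, mouse as a replicate block, all 4 regions in the mean, all 35 libraries for the regions, and leaving out each mouse. Added after the data were seen were limma voom on recovered reads, all small RNA classes tested together, removal of a linear GC trend, settings for the list tests, other scalings of the calls shared between regions, and, for the reversal, a slope, other scalings and 1000 draws that keep the genotype change. GC content came from the hairpin sequences in the reference and was available for 608 of 614 miRNAs (99.0%). Every split of the libraries of a comparison into groups of the same sizes was refitted, 10 for 3 against 3, and 100 were drawn for the WT regions. The brain stem comparisons with WT and the WT brain stem contrast were left out of the splits. On simulated data with the size of the 4L;C* against WT comparison in cerebellum, limma called 35.8% of changes of 0.5, 67.2% of changes of 1 and 86.4% of changes of 2 on the log2 scale, and 3.82% of its calls were false. The simulated miRNAs varied independently, without a trend or shift shared within a library. The share of false calls in the real libraries was thus not measured. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.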

Results

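Small RNA was sequenced from cerebellum, cortex, midbrain and brain stem of 9 mice aged 42 to 45 days. The mice formed 3 groups of 3: wild type (WT), 4L;C*, and 4L;C* treated with isofagomine (IFG). The 4L;C* mouse is a model of neuronopathic Gaucher disease that carries a Gba1 point-mutation allele, which affects the lysosomal enzyme glucocerebrosidase, together with a defect of saposin C, the activator of that enzyme. IFG is an iminosugar that binds glucocerebrosidase as a pharmacological chaperone, and it was given in drinking water at 60 mg/kg/day starting 3 to 5 days before birth. Of the 36 libraries, 35 carried a group label, which gave 11 groups of 3 and a WT brain stem group of 2, because the remaining WT brain stem library was labelled only as an outlier. Recovered mature miRNA reads per grouped library ranged from 688475 to 3045139, with the lowest depth in the 4L;C* midbrain (688475 to 1490285) and the highest in the 4L;C* cerebellum (2252656 to 3045139). These totals leave out 10 highly abundant miRNA names whose read level could not be recovered, so they understate the depth. Values below are log2 changes ± standard error (SE) from limma with n = 3 mice per group unless another n is given, and names are given without the species prefix mmu. Errors of group levels are standard deviations (SD).

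The WT libraries were first compared between regions, each against the mean of the others, to describe how miRNA levels differ across the normal brain. The cerebellum had higher miR-217-5p (4.55 ± 0.38) and miR-216a-5p (4.12 ± 0.63), neighbours on chromosome 11 that are abundant in the pancreas. The linked miR-195-5p (3.13 ± 0.11) and miR-497-5p (3.28 ± 0.10) were also higher there, while 3 members of the epithelial miR-200 family were lower, miR-429-3p at -4.24 ± 0.74, miR-200b-3p at -4.10 ± 0.91 and miR-200a-3p at -3.83 ± 1.05. Among the cerebellum-associated miRNAs, of 7, 6 were higher (6 higher and 1 lower adjusted over the list alone). Among the let-7 family, a set of abundant miRNAs that restrain proliferation, of 21, 15 were higher (16 higher adjusted over the list alone). Among erythroid miRNAs, of 9, 7 were higher (7 higher adjusted over the list alone), with miR-486-3p at 2.59 ± 0.25. In the Dlk1-Dio3 imprinted cluster, a maternally expressed miRNA domain on chromosome 12 active in neurons, of 79, 3 were higher and 49 were lower (3 higher and 49 lower adjusted over the list alone). In all, 345 of the 614 tested miRNAs passed limma at a Benjamini-Hochberg adjusted p of 0.05, 147 higher and 198 lower, with n = 3 for the cerebellum and 8 libraries elsewhere and a median of -0.18 over all tested.

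In the WT cortex, the neuron-enriched miR-128-1-5p was higher than in the other regions by 3.33 ± 0.11 and miR-128-3p by 1.81 ± 0.08, the CREB-induced miR-132-3p by 1.74 ± 0.10, and miR-221-3p by 2.13 ± 0.09. From the sensory-neuron cluster, miR-183-5p (-4.66 ± 0.62) and miR-182-5p (-4.39 ± 0.54) were lower, as were the Hox-cluster miR-10a-5p (-3.65 ± 0.12) and miR-10b-5p (-3.44 ± 0.17). By group, among forebrain-associated miRNAs, of 15, 12 were higher and 2 were lower (12 higher and 2 lower adjusted over the list alone). Among neuron-enriched ones, of 23, 14 were higher and 3 were lower (14 higher and 3 lower adjusted over the list alone). Of the Dlk1-Dio3 cluster, of 79, 46 were higher and 2 were lower (49 higher and 2 lower adjusted over the list alone). The limma fit called 281 of the 614 miRNAs at a Benjamini-Hochberg adjusted p of 0.05, 151 higher and 130 lower. The brain stem showed the opposite end of the Hox pattern, with miR-10b-5p at 6.16 ± 0.19 and miR-10a-5p at 6.13 ± 0.14. Also higher were, from the sensory cluster, miR-183-5p at 4.67 ± 0.71 and miR-96-5p at 4.62 ± 0.78, and the muscle miRNAs miR-1a-3p at 3.08 ± 0.33 and miR-133a-3p at 2.84 ± 0.13. The 2 brain stem libraries differed for the sensory cluster. Without WT mouse 6914, miR-183-5p was at 4.05 and miR-96-5p at 3.62, and without WT mouse 6912 they were at 5.57 and 5.84. Among oligodendrocyte miRNAs there, of 11, 7 were higher and 1 was lower (7 higher and 1 lower adjusted over the list alone), with miR-219-2-3p at 2.06 ± 0.10 and miR-338-3p at 1.80 ± 0.09, both linked to myelination. Among the 614 tested, 278 passed limma at a Benjamini-Hochberg adjusted p of 0.05, 139 higher and 139 lower, on 2 brain stem libraries against 9, and without the library of WT mouse 6914 the count was 163.

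The WT midbrain had higher miR-7a-2-3p (2.84 ± 0.22), miR-139-5p (2.62 ± 0.09) and miR-187-5p (2.49 ± 0.32) than the other regions. It had lower miR-34a-5p, a p53 target (-2.76 ± 0.15), miR-190-5p, from an intron of talin 2 (-2.48 ± 0.24), and the blood-cell miR-142-3p (-2.45 ± 0.33). Among miR-30 family members, of 11, 9 were lower (9 lower adjusted over the list alone). Among erythroid miRNAs, of 9, 7 were lower (8 lower adjusted over the list alone). Among vascular miRNAs, of 13, 4 were higher and 8 were lower (4 higher and 8 lower adjusted over the list alone). By limma with Benjamini-Hochberg adjustment, 322 of the 614 passed 0.05, 163 higher and 159 lower (148 and 175 after centring). Across miRNAs this contrast correlated with GC content at r = 0.279, and after removal of the GC trend 306 passed, 156 higher and 150 lower. A trait of the WT midbrain libraries was not told apart from a regional difference. When the contrast was instead averaged over all 35 libraries, miR-138-5p changed sign in the midbrain, from -0.59 ± 0.10 to 0.24.

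The effect of genotype was asked in each region by comparing untreated 4L;C* with WT. In the cerebellum, miR-155-5p, induced in activated macrophages and microglia (chromosome 16, end 84714410), rose 2.86-fold (1.52 ± 0.28, adjusted p = 0.000218), from 4.55 ± 0.13 to 6.07 ± 0.22 log2 scaled reads (SD). It rested on 32 to 34 reads per WT library and 80 to 113 per 4L;C* library. MiR-146a-5p, an NF-kappaB-induced repressor of IRAK1 and TRAF6, rose by 1.27 ± 0.31. MiR-98-3p fell 15.4-fold (-3.94 ± 0.45, chromosome X, end 148347851) and miR-301a-3p, from an intron of Ska2, fell 9.69-fold (-3.28 ± 0.42, chromosome 11, end 86926578). Without mouse 5186 these log2 changes were -4.61 and -4.14, and without 5187 that of miR-301a-3p was -2.61. MiR-5117-5p had the largest rise (2.67 ± 0.61). Other rises were miR-3096b-5p (1.76 ± 0.35) and miR-92a-1-5p (1.57 ± 0.38), and other falls included the oligodendrocyte miR-219-5p (-1.55 ± 0.39) and the p53-regulated miR-34b-5p (-1.90 ± 0.35).

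By group in the 4L;C* cerebellum, among let-7 family members, 7 of 21 rose, 7 fell and 7 did not pass (9 higher and 8 lower adjusted over the list alone). The 7 that rose were 5p arms such as let-7c-5p (0.93 ± 0.13), and the 7 that fell were 3p arms such as let-7a-1-3p (-1.87 ± 0.25) and let-7c-2-3p (-1.87 ± 0.24). Let-7a-1-3p and let-7c-2-3p moved nearly alike in every region and may hold the same reads. Among microglia and haematopoietic miRNAs, 4 of 13 rose, 1 fell and 8 did not pass (5 higher and 1 lower adjusted over the list alone). Neuronal activity-regulated miRNAs went both ways: 4 of 16 rose, 3 fell and 9 did not pass (5 higher and 3 lower adjusted over the list alone), with miR-212-5p at 0.67 ± 0.14, miR-132-3p at 0.50 ± 0.13 and miR-181c-5p at -0.76 ± 0.22. In the miR-30 family, 4 of 11 fell and 7 did not pass (4 lower adjusted over the list alone), with miR-30e-5p at -1.18 ± 0.25. The erythroid miR-144-3p fell by 2.41 ± 0.53 and miR-16-2-3p by 2.08 ± 0.52 on the log2 scale. The lipid regulator miR-33-5p, from an intron of Srebf2 and a repressor of Abca1, fell by 3.08 ± 0.75. No list reached an adjusted p of 0.05 by camera. In all, 114 of the 614 tested miRNAs passed limma at a Benjamini-Hochberg adjusted p of 0.05, 52 higher and 62 lower. The fit of the 2 groups alone gave 71, and the count fell to 47 without the 4L;C* mouse 5187.

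In the 4L;C* cortex, miR-155-5p rose 4.36-fold (2.12 ± 0.28, adjusted p = 1.15e-06), miR-5117-5p by 2.53 ± 0.61, miR-1251-5p by 1.43 ± 0.42 and the hindbrain Hox-cluster miR-10a-5p by 1.15 ± 0.26. The neuronal activity miRNA miR-132-5p rose by 0.93 ± 0.18 and miR-212-5p by 0.64 ± 0.14. MiR-193-3p (-2.83 ± 0.58), miR-301a-3p (-2.59 ± 0.42), miR-218-2-3p, from an intron of Slit3 (-2.58 ± 0.54), and the imprinted-cluster miR-377-3p (-1.93 ± 0.42) were among the largest falls. Among let-7 5p arms, let-7f-5p went from 15.97 ± 0.01 to 17.08 ± 0.11 (SD), a rise of 1.11 ± 0.14, miR-98-5p rose by 1.23 ± 0.15 and let-7i-5p by 0.92 ± 0.10.

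Cortical lists with a directional call included let-7, where 8 of 21 rose, 3 fell and 10 did not pass (8 higher and 3 lower adjusted over the list alone). Camera gave adjusted p = 0.0139, adjusted p = 0.592 with an estimated correlation, adjusted p = 0.0517 after removal of a GC trend. It passed in 8 of 9 fits without 1 mouse. Inflammation-responsive miRNAs were called too, and 3 of 15 rose and 12 did not pass (6 higher adjusted over the list alone). The list test gave adjusted p = 0.0139, adjusted p = 0.287 with an estimated correlation. It passed in 8 of 9 fits without 1 mouse. The forebrain-associated list was also called: 3 of 15 rose, 1 fell and 11 did not pass (4 higher and 1 lower adjusted over the list alone). The directional test gave adjusted p = 0.0499, adjusted p = 0.592 with an estimated correlation, adjusted p = 0.0830 with each library centred on its median. It passed in 3 of 9 fits without 1 mouse. The 3 risers were miR-132-5p, miR-132-3p (0.63 ± 0.13) and miR-212-5p. In the cholesterol and lipid list, 5 of 17 rose, 1 fell and 11 did not pass (6 higher and 1 lower adjusted over the list alone), with miR-27b-3p at 0.61 ± 0.11. Of oligodendrocyte miRNAs, 2 of 11 fell and 9 did not pass (2 lower adjusted over the list alone), with miR-338-3p at -0.77 ± 0.22. The limma fit called 83 of the 614 miRNAs at a Benjamini-Hochberg adjusted p of 0.05, 35 higher and 48 lower. Without WT mouse 6913 or 6912 the count was 54 or 55.

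The 4L;C* midbrain had the most changed miRNAs of the 4 regions. MiR-190b-5p rose 6.38-fold (2.67 ± 0.53), the blood-cell miR-142-3p by 2.39 ± 0.45, miR-190-5p by 2.12 ± 0.35, the STAT3-induced miR-21-5p by 1.34 ± 0.17 and miR-155-5p by 1.28 ± 0.28. The let-7 5p arms let-7i-5p (1.62 ± 0.10), miR-98-5p (1.94 ± 0.15) and let-7f-5p (1.53 ± 0.14) rose, and let-7b-3p fell 4.96-fold (-2.31 ± 0.23), as did let-7a-2-3p (-1.98 ± 0.44) and miR-669c-5p (-2.23 ± 0.33). MiR-219-5p rose by 1.73 ± 0.39, whereas the related miR-219-2-3p fell by 0.82 ± 0.12. The muscle miRNAs miR-133a-3p (-0.83 ± 0.20) and miR-1a-3p (-1.75 ± 0.51) fell. Without 4L;C* mouse 5188, miR-1a-3p was at -0.90 and did not pass limma (adjusted p = 0.153). The contrast of WT midbrain with the other regions uses the same WT libraries, and miR-190-5p and miR-142-3p were lower there. Across miRNAs the genotype change correlated with GC content at r = -0.242, against r = 0.279 for that WT contrast. A trait of the WT midbrain libraries was thus not told apart from a genotype effect.

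There were 4 lists called higher in the 4L;C* midbrain. Among neuron-enriched miRNAs, 5 of 23 rose, 1 fell and 17 did not pass (5 higher and 1 lower adjusted over the list alone), with miR-9-5p at 0.79 ± 0.14 and miR-128-3p at 0.52 ± 0.11. Among inflammation-responsive ones, 4 of 15 rose, 1 fell and 10 did not pass (4 higher and 1 lower adjusted over the list alone). Among astrocyte-associated ones, 4 of 10 rose and 6 did not pass (4 higher adjusted over the list alone), with miR-26a-1-3p at 2.86 ± 0.66. In the miR-30 family, 6 of 11 rose, 2 fell and 3 did not pass (7 higher and 2 lower adjusted over the list alone) with miR-30a-5p at 0.96 ± 0.12 and miR-30c-5p at -0.79 ± 0.13. Each had adjusted p = 0.0459 by camera and adjusted p = 0.344 with an estimated correlation. None passed after removal of a GC trend (adjusted p from 0.0645 to 0.0726) or in every fit without 1 mouse (4 to 7 of 9). The Dlk1-Dio3 cluster was not called: 7 of 79 rose, 21 fell and 51 did not pass (7 higher and 23 lower adjusted over the list alone), with miR-667-3p at -1.33 ± 0.17. The set test gave adjusted p = 0.393. In the miR-181 family, 1 of 7 rose, 3 fell and 3 did not pass (1 higher and 4 lower adjusted over the list alone), with miR-181d-5p at 0.80 ± 0.11 and miR-181a-5p at -0.84 ± 0.12. In the cholesterol and lipid list, 8 of 17 rose, 3 fell and 6 did not pass (8 higher and 3 lower adjusted over the list alone). Among the 614 tested, 201 passed limma at a Benjamini-Hochberg adjusted p of 0.05, 78 higher and 123 lower (95 and 111 after centring, 99 and 108 after quantile normalization). The median over all tested miRNAs was -0.19, and the same libraries had higher tRNA-derived reads (82 of 245 features higher, median 0.77) and lower snoRNA reads (98 of 297 lower, median -0.29) than WT.

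In the 4L;C* brain stem, most miRNAs that changed were lower than in the 2 WT libraries. MiR-301a-3p fell 13.4-fold (-3.75 ± 0.47), and of the p53-regulated miR-34 family miR-34a-5p fell 4.27-fold (-2.09 ± 0.27), miR-34b-5p by 2.40 ± 0.39 and miR-34c-5p by 1.70 ± 0.38. The size of the last 2 falls depended on the WT library. Without WT mouse 6912, miR-34b-5p was at -3.10 and miR-34c-5p at -2.36, and without WT mouse 6914 they were at -1.70 and -1.04. The muscle miR-1a-3p (-2.30 ± 0.57) and miR-133a-3p (-0.89 ± 0.22), the endothelial miR-126-5p (-0.92 ± 0.22) and the neuronal miR-138-5p (-1.38 ± 0.19) also fell. Against this, miR-155-5p rose 6.74-fold (2.75 ± 0.31, adjusted p = 1.26e-07), from 4.71 ± 0.19 (n = 2) to 7.46 ± 0.07 (n = 3). MiR-146a-5p (1.38 ± 0.35), miR-455-3p (2.06 ± 0.51) and miR-5117-5p (2.94 ± 0.68) rose as well.

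The microglia and haematopoietic list was called higher in the brain stem: 2 of 13 rose and 11 did not pass (2 higher adjusted over the list alone). It had adjusted p = 0.0122 by camera and adjusted p = 0.0290 with an estimated correlation, the only one of the 28 list calls made over all comparisons that held with an estimated correlation. Its 2 risers, miR-155-5p and miR-146a-5p, also carried the inflammation-responsive call, where 2 of 15 rose, 1 fell and 12 did not pass (2 higher and 1 lower adjusted over the list alone). Tested as a set, it had adjusted p = 0.0451, adjusted p = 0.420 with an estimated correlation. It passed in 4 of 9 fits without 1 mouse. In the miR-34 family, 4 of 6 fell and 2 did not pass (4 lower adjusted over the list alone). By camera it had adjusted p = 0.0451, adjusted p = 0.464 with an estimated correlation. It passed in 4 of 9 fits without 1 mouse. In the Dlk1-Dio3 cluster, 1 of 79 rose, 28 fell and 50 did not pass (1 higher and 32 lower adjusted over the list alone), with a median of -0.48 against -0.33 for all tested. As a set it had adjusted p = 0.0451, adjusted p = 0.606 with an estimated correlation, adjusted p = 0.218 with each library centred on its median. It passed in 4 of 9 fits without 1 mouse. In the vascular list, 6 of 13 fell and 7 did not pass (7 lower adjusted over the list alone). Of oligodendrocyte miRNAs, 4 of 11 fell and 7 did not pass (4 lower adjusted over the list alone), and of muscle miRNAs, 3 of 6 fell and 3 did not pass (3 lower adjusted over the list alone). By limma with Benjamini-Hochberg adjustment, 164 of the 614 passed 0.05, 24 higher and 140 lower. The median of all tested miRNAs was -0.33, and with each library centred on its median 109 passed, 50 higher and 59 lower (117 after quantile normalization, 69 higher and 48 lower), so the scaling decided which direction was more frequent. WT had only 2 libraries, and without WT mouse 6914 or 6912 the count was 73 or 103.

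With the mouse as the replicate, averaging cerebellum, cortex and midbrain, genotype changed miR-5117-5p (2.60 ± 0.60), miR-155-5p (1.64 ± 0.18), miR-190b-5p (1.63 ± 0.28) and miR-1251-5p (1.55 ± 0.20) on the higher side. On the lower side stood miR-301a-3p (-1.91 ± 0.25), let-7a-2-3p (-1.79 ± 0.30), miR-218-2-3p (-1.75 ± 0.25) and let-7b-3p (-1.55 ± 0.12). MiR-301a-3p did not move this way in the midbrain (0.15 ± 0.42, not passed). The inflammation-responsive list was called higher: 8 of 15 rose and 7 did not pass (8 higher adjusted over the list alone). Its test gave adjusted p = 0.00946, adjusted p = 0.533 with an estimated correlation, led by miR-155-5p, miR-146a-5p (0.88 ± 0.11), miR-21-5p (0.64 ± 0.09) and miR-132-5p (0.71 ± 0.11). In all, 225 of the 614 tested miRNAs passed limma at a Benjamini-Hochberg adjusted p of 0.05, 98 higher and 127 lower.

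The other lists were not called in this averaged comparison, and their members divided as follows. Among microglia and haematopoietic miRNAs, 4 of 13 rose and 9 did not pass (4 higher adjusted over the list alone), including miR-223-3p at 0.69 ± 0.19 and miR-142-3p at 0.87 ± 0.21, the latter against -0.52 ± 0.45 in the cerebellum (not passed). In the neuron-enriched list, 8 of 23 rose, 1 fell and 14 did not pass (8 higher and 1 lower adjusted over the list alone), including miR-9-5p at 0.39 ± 0.08. Of activity-regulated miRNAs, 3 of 16 rose, 4 fell and 9 did not pass (3 higher and 4 lower adjusted over the list alone). Of forebrain-associated ones, 5 of 15 rose, 1 fell and 9 did not pass (5 higher and 1 lower adjusted over the list alone), and both lists hold the rising miR-132-5p and miR-212-5p (0.47 ± 0.09). Oligodendrocyte miRNAs went both ways, in that 2 of 11 rose, 2 fell and 7 did not pass (2 higher and 2 lower adjusted over the list alone), with miR-338-3p at -0.56 ± 0.10 and miR-338-5p at 0.56 ± 0.11. For the astrocyte-associated list, 4 of 10 rose and 6 did not pass (4 higher adjusted over the list alone). Of vascular miRNAs, 4 of 13 rose, 1 fell and 8 did not pass (4 higher and 1 lower adjusted over the list alone). Of erythroid ones, 3 of 9 rose, 2 fell and 4 did not pass (3 higher and 2 lower adjusted over the list alone), with miR-451 at 0.29 ± 0.10 and miR-486-3p at -0.52 ± 0.17. In the choroid plexus and ciliated epithelium list, 1 of 14 rose, 2 fell and 11 did not pass (1 higher and 2 lower adjusted over the list alone). The 2 that fell were miR-34b-5p (-0.79 ± 0.15) and miR-34c-5p (-0.48 ± 0.11), against 0.72 ± 0.35 and 0.49 ± 0.34 in the midbrain (not passed). In the Hox-cluster hindbrain list, 1 of 3 rose and 2 did not pass (1 higher adjusted over the list alone), namely miR-10a-5p (0.83 ± 0.15). Among cerebellum-associated miRNAs, 3 of 7 fell and 4 did not pass (4 lower adjusted over the list alone).

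In the Dlk1-Dio3 cluster, 8 of 79 rose, 21 fell and 50 did not pass (8 higher and 21 lower adjusted over the list alone), with miR-127-5p at -1.06 ± 0.10 and miR-382-5p at 1.24 ± 0.12. Among the let-7 family, 8 of 21 rose, 8 fell and 5 did not pass (9 higher and 8 lower adjusted over the list alone). They divided by arm, with the 5p arms at a median of 0.70 and the 3p arms at -0.56. In the miR-17-92 list, 2 of 18 rose, 3 fell and 13 did not pass (2 higher and 3 lower adjusted over the list alone). Of the miR-29 family, 1 of 7 rose, 2 fell and 4 did not pass (1 higher and 2 lower adjusted over the list alone). Of the miR-30 family, 3 of 11 rose, 3 fell and 5 did not pass (3 higher and 3 lower adjusted over the list alone). Of the miR-34 family, 3 of 6 fell and 3 did not pass (3 lower adjusted over the list alone). In the miR-181 family, 1 of 7 rose, 4 fell and 2 did not pass (1 higher and 4 lower adjusted over the list alone), with miR-181c-5p at -0.95 ± 0.10. In the miR-183 cluster, none of the 3 passed in the limma fit (0 higher and 0 lower adjusted over the list alone, 0 higher and 0 lower at an unadjusted p under 0.05). In the alpha-synuclein and Parkinson-associated list, 2 of 14 fell and 12 did not pass (2 lower adjusted over the list alone), both from the miR-34 family, while miR-7a-5p and miR-7b-5p, which target alpha-synuclein mRNA, did not pass. In the glucocerebrosidase-associated list, 1 of 7 rose, 2 fell and 4 did not pass (1 higher and 3 lower adjusted over the list alone), with miR-16-5p up (0.24 ± 0.09) and miR-127-5p and miR-195-3p down. Among autophagy and lysosome miRNAs, 7 of 27 rose, 4 fell and 16 did not pass (8 higher and 5 lower adjusted over the list alone), including the beclin 1 repressor miR-30a-5p at 0.50 ± 0.08. In the cholesterol and lipid list, 6 of 17 rose, 2 fell and 9 did not pass (7 higher and 3 lower adjusted over the list alone). Of muscle miRNAs, 2 of 6 fell and 4 did not pass (3 lower adjusted over the list alone), miR-1a-3p and miR-133a-3p.

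Across the 4 regions, 4 miRNAs were higher in 4L;C* than WT in every region (let-7a-5p, let-7c-5p, miR-155-5p and miR-5117-5p) and 9 were lower in every region: let-7b-3p, miR-148b-5p, miR-181c-5p, miR-3085-3p, miR-3102-3p.2-3p, miR-34a-5p, miR-377-3p, miR-381-3p and miR-490-3p. Those found in every region were counted with the deposited scaling only, under which the brain stem median was -0.33. Cerebellum and brain stem shared 48 lower miRNAs where 14.1 were expected by chance, but cerebellum and midbrain shared 12 where 12.4 were expected, and 13 higher miRNAs where 6.61 were expected. With each library centred on its median the shared falls were 38 against 5.96 and 10 against 11.2, and after quantile normalization 30 against 4.85 and 12 against 10.9. The difference of the genotype effect between regions was tested itself with limma, and 172 miRNAs passed. Let-7i-5p had a change of 0.28 ± 0.10 in the cerebellum (not passed), 0.92 ± 0.10 in the cortex, 1.62 ± 0.10 in the midbrain and 0.37 ± 0.12 in the brain stem (adjusted p of the difference = 2.40e-07). MiR-30a-5p rose in cortex (0.61 ± 0.12) and midbrain (0.96 ± 0.12) but fell in brain stem (-0.48 ± 0.13). The endothelial miR-126-5p rose in midbrain (0.99 ± 0.19) but fell in brain stem (-0.92 ± 0.22), and miR-190-5p did the same (2.12 ± 0.35 and -1.44 ± 0.39). The brain stem values stand around a median of -0.33 over all tested miRNAs, which was -0.03 with each library centred on its median. MiR-342-3p, of blood cells, rose in cerebellum (0.60 ± 0.12) and fell in midbrain (-0.62 ± 0.12). Without WT mouse 6912 or 6914 the count of differing miRNAs was 114 in either case. The midbrain values carry the limit given above on the WT midbrain libraries.

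**Figure D1:**
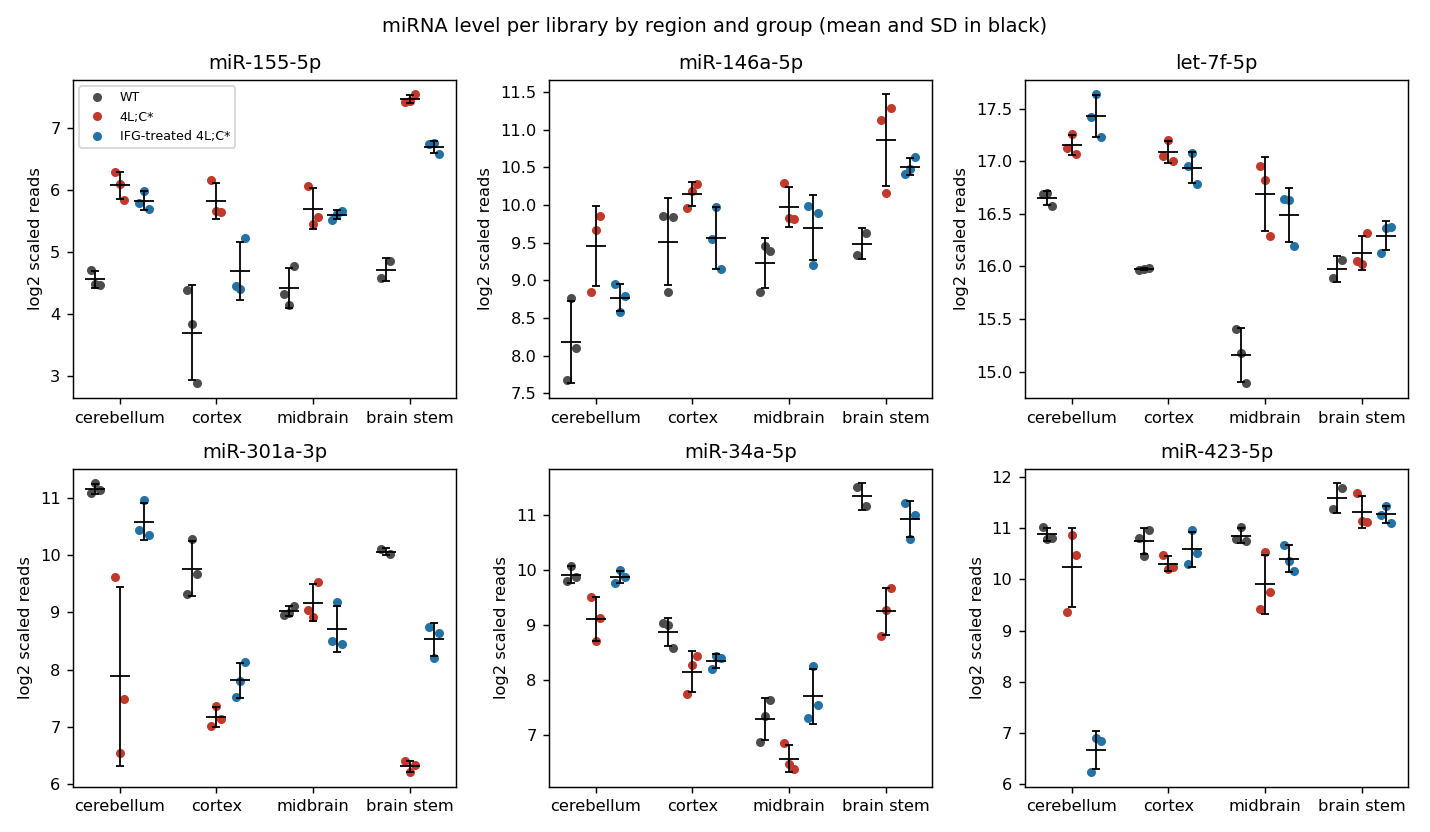
Level of 6 miRNAs in each library, in log2 scaled reads, by region and group, with points for libraries and black bars for mean and SD (n = 3, but 2 for WT brain stem). MiR-155-5p rose in 4L;C* over WT in all 4 regions (log2 changes from 1.28 to 2.75), and miR-423-5p was low in the IFG-treated cerebellum (6.66 ± 0.37 against 10.23 ± 0.78 untreated).

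The effect of the chaperone was asked by comparing IFG-treated with untreated 4L;C* mice. In the cerebellum, miR-423-5p fell 11.9-fold (-3.58 ± 0.28, chromosome 11, end 76891646, adjusted p = 2.04e-10), on 69 to 98 reads per treated library against 958 to 2384 per untreated one. MiR-298-5p (-1.96 ± 0.18), miR-9-3p, an opponent of the REST cofactor CoREST (-1.58 ± 0.30), and miR-877-5p (-1.48 ± 0.25) fell as well. MiR-301a-3p, low in the untreated mutant, rose 6.5-fold (2.70 ± 0.42, but 3.56 without mouse 5186 and 2.03 without 5187), and miR-101a-3p (1.85 ± 0.30), the dendritic miR-134-5p (1.60 ± 0.15) and its cluster neighbour miR-379-5p (1.51 ± 0.21) rose. Let-7a-5p (1.23 ± 0.13) and let-7c-5p (1.13 ± 0.13), already above WT in the untreated mice, rose further. After quantile normalization let-7a-5p was at 0.58, and let-7c-5p at 0.48 without a call (adjusted p = 0.0629). The median of all let-7 5p arms went from 0.81 to 0.33. The treated cerebellar libraries also stood apart in total scaled mature reads (log2 21.17 to 21.35, at most 20.90 in other groups), and the cause was not tested.

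The miR-181 family, a set of neuronal and lymphoid miRNAs, was called higher in the treated cerebellum, where 4 of 7 rose and 3 did not pass (5 higher adjusted over the list alone), with miR-181d-5p at 0.89 ± 0.11. Camera gave adjusted p = 0.0130, adjusted p = 0.988 with an estimated correlation. The let-7 family was also called, and 9 of 21 rose, 1 fell and 11 did not pass (9 higher and 2 lower adjusted over the list alone). The list test gave adjusted p = 0.0349, adjusted p = 0.988 with an estimated correlation, adjusted p = 0.0709 with each library centred on its median. It passed in 6 of 9 fits without 1 mouse. In the Dlk1-Dio3 cluster, 14 of 79 rose, 1 fell and 64 did not pass (15 higher and 1 lower adjusted over the list alone). The directional test gave adjusted p = 0.235. The limma fit called 93 of the 614 miRNAs at a Benjamini-Hochberg adjusted p of 0.05, 70 higher and 23 lower. The split became 41 higher and 26 lower after quantile normalization and 52 higher and 28 lower after centring. The 2 groups alone gave 48, and the count was 61, 58 or 53 without 4L;C* mouse 5187, 5188 or IFG mouse 5754.

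In the cortex, miR-5117-5p (-2.47 ± 0.61, but -3.27 without mouse 5755) and miR-155-5p (-1.13 ± 0.28, adjusted p = 0.0144), both higher in untreated 4L;C* than in WT, fell with treatment. So did the let-7 passenger arms miR-98-3p (-2.29 ± 0.45) and let-7a-1-3p (-1.83 ± 0.25). MiR-187-5p (2.45 ± 0.41) and miR-218-2-3p (2.15 ± 0.54), both lower in untreated 4L;C* than in WT, rose, and so did miR-99a-3p (1.2 ± 0.21) and the imprinted miR-341-3p (1.02 ± 0.23). Among the let-7 family, 4 of 21 fell and 17 did not pass (5 lower and 1 higher adjusted over the list alone), all 3p arms. The set test gave adjusted p = 1.59e-06, adjusted p = 0.341 with an estimated correlation. Among inflammation-responsive miRNAs, 2 of 15 fell and 13 did not pass (2 lower adjusted over the list alone), namely miR-155-5p and miR-9-3p (-1.19 ± 0.30). Tested as a set, it had adjusted p = 0.0126, adjusted p = 0.35 with an estimated correlation. It passed in 7 of 9 fits without 1 mouse. Of the Dlk1-Dio3 cluster, 3 of 79 rose and 76 did not pass (9 higher and 1 lower adjusted over the list alone). By camera it had adjusted p = 0.00390, adjusted p = 0.376 with an estimated correlation. In the miR-181 family, none of the 7 passed in the limma fit (5 higher and 0 lower adjusted over the list alone, 5 higher and 0 lower at an unadjusted p under 0.05). As a set it had adjusted p = 0.00390, adjusted p = 0.376 with an estimated correlation. It passed in 8 of 9 fits without 1 mouse. Among the 614 tested, 20 passed limma at a Benjamini-Hochberg adjusted p of 0.05, 12 higher and 8 lower, around a median of 0.13, and centring gave 4 higher and 10 lower (quantile normalization 5 and 9). The 2 groups alone gave 13, and the count was 5, 9 or 9 without mouse 5186, 5754 or 5755.

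In the midbrain, treatment raised miR-218-2-3p (1.77 ± 0.54), the muscle miR-1a-3p (1.73 ± 0.51), miR-106b-5p (1.5 ± 0.35), miR-34a-5p (1.13 ± 0.24) and miR-383-5p (0.90 ± 0.15). It lowered miR-98-3p (-2.49 ± 0.45), let-7c-2-3p (-2.16 ± 0.24), miR-9-3p (-2.10 ± 0.30), miR-5117-5p (-2.09 ± 0.61, but -2.78 without mouse 5755) and miR-30e-3p (-1.42 ± 0.18). Without 4L;C* mouse 5188, miR-218-2-3p was at 1.07 and miR-1a-3p at 0.87, and neither passed limma (adjusted p = 0.288 and 0.324). Among let-7 members, 6 of 21 fell and 15 did not pass (6 lower adjusted over the list alone). Its test gave adjusted p = 0.00435, adjusted p = 0.662 with an estimated correlation. It passed in 7 of 9 fits without 1 mouse. The median of the family was 0.000666, on the other side of 0, and of the 6 only let-7i-5p is a 5p arm. In the Dlk1-Dio3 cluster, 13 of 79 rose and 66 did not pass (16 higher and 1 lower adjusted over the list alone), with miR-411-5p at 0.83 ± 0.15. Camera gave adjusted p = 0.0138, adjusted p = 0.662 with an estimated correlation. It passed in 7 of 9 fits without 1 mouse. In the miR-29 family, 3 of 7 fell and 4 did not pass (3 lower adjusted over the list alone), all 5p arms such as miR-29a-5p (-1.22 ± 0.27). The list test gave adjusted p = 0.0446, adjusted p = 0.662 with an estimated correlation, adjusted p = 0.0602 after removal of a GC trend. It passed in 5 of 9 fits without 1 mouse. By limma with Benjamini-Hochberg adjustment, 85 of the 614 passed 0.05, 58 higher and 27 lower, around a median of 0.18 (39 higher and 43 lower after quantile normalization). The 2 groups alone gave 4, and the count was 38, 150, 23 or 45 without mouse 5186, 5187, 5188 or 5754.

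In the brain stem, many miRNAs that were lower in untreated 4L;C* than in WT were higher after treatment. Of the miR-34 family, miR-34b-5p rose 6.95-fold (2.80 ± 0.35), miR-34c-5p by 1.92 ± 0.34 and miR-34a-5p by 1.68 ± 0.24. Other rises were miR-301a-3p at 2.22 ± 0.42, miR-193-3p at 2.19 ± 0.58, miR-1a-3p at 2.00 ± 0.51 and the oligodendrocyte miR-219-5p at 1.69 ± 0.39. Falls were fewer: miR-5117-5p (-2.17 ± 0.61, but -2.76 without mouse 5755), miR-455-3p (-2.04 ± 0.46), miR-3096-5p (-1.59 ± 0.44) and miR-155-5p (-0.77 ± 0.28, adjusted p = 0.0427). In the miR-34 family, 4 of 6 rose and 2 did not pass (4 higher adjusted over the list alone). The directional test gave adjusted p = 0.00168, adjusted p = 0.248 with an estimated correlation. In the alpha-synuclein and Parkinson-associated list, 7 of 14 rose and 7 did not pass (10 higher adjusted over the list alone). The set test gave adjusted p = 0.00390, adjusted p = 0.248 with an estimated correlation. The risers were 3 miR-34 arms, both miR-214 arms (miR-214-5p at 2.64 ± 0.60), the muscle miR-133b-3p (1.25 ± 0.30) and miR-7b-5p, which represses alpha-synuclein (0.78 ± 0.29). The let-7 family was called lower although 1 of 21 fell and 20 did not pass (0 lower adjusted over the list alone), let-7f-1-3p (-1.21 ± 0.41). Tested as a set, it had adjusted p = 0.00121, adjusted p = 0.354 with an estimated correlation. Of the Dlk1-Dio3 cluster, 27 of 79 rose, 1 fell and 51 did not pass (32 higher and 1 lower adjusted over the list alone). By camera it had adjusted p = 0.0560. Of muscle miRNAs, 3 of 6 rose and 3 did not pass (4 higher adjusted over the list alone). Among autophagy and lysosome miRNAs, 10 of 27 rose, 1 fell and 16 did not pass (11 higher and 1 lower adjusted over the list alone). In all, 146 of the 614 tested miRNAs passed limma at a Benjamini-Hochberg adjusted p of 0.05, 137 higher and 9 lower. The median was 0.27, and centring left 76, 35 higher and 41 lower (quantile normalization 84, 42 and 42), while the count was 68, 93 or 89 without mouse 5186, 5755 or 5187.

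Averaged over cerebellum, cortex and midbrain by mouse, treatment raised miR-218-2-3p (1.86 ± 0.25), miR-99a-3p (1.19 ± 0.12), miR-193-3p (1.14 ± 0.23) and miR-341-3p (1.01 ± 0.14). MiR-301a-3p rose too (0.96 ± 0.25), without a call when mouse 5188, 5754 or 5755 was left out. In the midbrain miR-193-3p was at -0.25 ± 0.58 and miR-301a-3p at -0.46 ± 0.42 (not passed). It lowered miR-9-3p (-1.62 ± 0.12), let-7a-1-3p (-1.45 ± 0.12), miR-98-3p (-1.08 ± 0.26) and miR-423-5p (-0.93 ± 0.16). MiR-146a-5p (-0.52 ± 0.11) and miR-155-5p (-0.49 ± 0.18) fell, though of the averaged regions miR-155-5p passed by itself only in the cortex. The miR-181 family was called higher, where 6 of 7 rose and 1 did not pass (6 higher adjusted over the list alone). As a set it had adjusted p = 0.0112, adjusted p = 0.848 with an estimated correlation. Among Dlk1-Dio3 cluster miRNAs, 30 of 79 rose, 3 fell and 46 did not pass (33 higher and 3 lower adjusted over the list alone), with miR-127-5p at 0.79 ± 0.10. Its test gave adjusted p = 0.00400, adjusted p = 0.848 with an estimated correlation. The limma fit called 162 of the 614 miRNAs at a Benjamini-Hochberg adjusted p of 0.05, 122 higher and 40 lower, around a median of 0.12. The split was 93 higher and 53 lower after centring and 76 and 66 after quantile normalization, and the count was 103 without mouse 5186. In every region treatment raised 2 miRNAs, miR-341-3p and miR-99a-3p, counted with the deposited scaling only. The treatment effect differed between regions for 66 miRNAs by its own limma test, and for 39 or 40 without IFG mouse 5754 or 5755. MiR-423-5p and miR-298-5p had the smallest p (adjusted p of the difference = 1.35e-08 each), with miR-423-5p at 0.29 ± 0.28 in cortex, 0.50 ± 0.28 in midbrain and -0.05 ± 0.28 in brain stem beside its cerebellar fall. MiR-98-3p rose with treatment in the cerebellum (1.55 ± 0.45) and fell in cortex and midbrain (adjusted p of the difference = 4.37e-05).

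What differed from WT under treatment was asked by comparing IFG-treated 4L;C* with WT. In the cerebellum, let-7c-5p stood 4.16-fold above WT (2.06 ± 0.13), let-7a-5p at 1.88 ± 0.13, miR-134-5p at 1.77 ± 0.15 and miR-155-5p at 1.27 ± 0.28. MiR-423-5p stood 18.7-fold below WT (-4.22 ± 0.28), miR-9-3p at -2.60 ± 0.30, miR-98-3p at -2.39 ± 0.45 and the muscle miR-499-5p at -1.85 ± 0.54. Among let-7 members, 9 of 21 rose, 7 fell and 5 did not pass (10 higher and 9 lower adjusted over the list alone). Of the Dlk1-Dio3 cluster, 13 of 79 rose, 7 fell and 59 did not pass (13 higher and 7 lower adjusted over the list alone). Among the 614 tested, 134 passed limma at a Benjamini-Hochberg adjusted p of 0.05, 89 higher and 45 lower (66 higher and 54 lower after quantile normalization). In the cortex, miR-98-5p (1.00 ± 0.15), let-7f-5p (0.96 ± 0.14), miR-155-5p (0.99 ± 0.28) and miR-132-5p (0.72 ± 0.18) stayed higher and miR-301a-3p (-1.95 ± 0.42) lower. MiR-98-3p was lower (-2.72 ± 0.45), which it was not by test in untreated mice (-0.44 ± 0.45, adjusted p = 0.587). By limma with Benjamini-Hochberg adjustment, 57 of the 614 passed 0.05, 40 higher and 17 lower, around a median of 0.14. Centring left 34, 11 higher and 23 lower (quantile normalization 34, 14 and 20), the 2 groups alone gave 137, and the count was 35 or 29 without mouse 6914 or 5754.

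In the treated midbrain, miR-142-3p (2.55 ± 0.45), miR-190b-5p (2.44 ± 0.53), miR-188-5p (2.05 ± 0.30) and miR-21-5p (1.37 ± 0.17) were above WT, and let-7f-1-3p (-2.77 ± 0.41), miR-98-3p (-2.56 ± 0.45) and miR-29b-1-5p (-2.17 ± 0.39) below. In all, 137 of the 614 tested miRNAs passed limma at a Benjamini-Hochberg adjusted p of 0.05, 71 higher and 66 lower (72 and 76 after quantile normalization). The treated brain stem came closest to WT in count, with higher miR-193-3p (2.69 ± 0.65), miR-155-5p (1.98 ± 0.31) and miR-99a-3p (1.53 ± 0.23), and lower miR-98-3p (-3.0 ± 0.50) and the myelin-linked miR-219-2-3p (-0.85 ± 0.13). Among microglia and haematopoietic miRNAs there, 1 of 13 rose and 12 did not pass (3 higher adjusted over the list alone). Camera gave adjusted p = 0.0357, adjusted p = 0.0636 with an estimated correlation. It passed in 8 of 9 fits without 1 mouse. In the miR-30 family, none of the 11 passed in the limma fit (0 higher and 1 lower adjusted over the list alone, 0 higher and 2 lower at an unadjusted p under 0.05). The list test gave adjusted p = 0.0480, adjusted p = 0.295 with an estimated correlation, adjusted p = 0.0514 after removal of a GC trend. It passed in 5 of 9 fits without 1 mouse. The limma fit called 19 of the 614 miRNAs at a Benjamini-Hochberg adjusted p of 0.05, 6 higher and 13 lower, on 2 WT libraries. The 2 groups alone gave 63, and the count was 12, 11 or 9 without mouse 5755, 6912 or 6914.

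Averaged by mouse over 3 regions, treated mice had higher miR-190b-5p (1.58 ± 0.28), miR-98-5p (1.30 ± 0.09), miR-155-5p (1.15 ± 0.18) and let-7c-5p (1.15 ± 0.09) than WT. They had lower miR-98-3p (-2.55 ± 0.26), let-7f-1-3p (-2.04 ± 0.32), miR-9-3p (-1.73 ± 0.12) and miR-423-5p (-1.61 ± 0.16), the last against -0.15 ± 0.28 in cortex and -0.45 ± 0.28 in midbrain (not passed). All 9 measured let-7 5p arms rose (median 1.00) and 9 of 12 3p arms fell (median -1.2), and neither median changed sign under another scaling. The 3p arms include let-7a-1-3p and let-7c-2-3p, which moved nearly alike in every region and may hold the same reads. Inflammation-responsive miRNAs divided so that 8 of 15 rose, 1 fell and 6 did not pass (8 higher and 1 lower adjusted over the list alone). The directional test gave adjusted p = 0.171. Of microglia and haematopoietic miRNAs, 6 of 13 rose and 7 did not pass (6 higher adjusted over the list alone). Among the 614 tested, 158 passed limma at a Benjamini-Hochberg adjusted p of 0.05, 106 higher and 52 lower (91 and 59 after centring, 82 and 69 after quantile normalization).

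**Figure D2:**
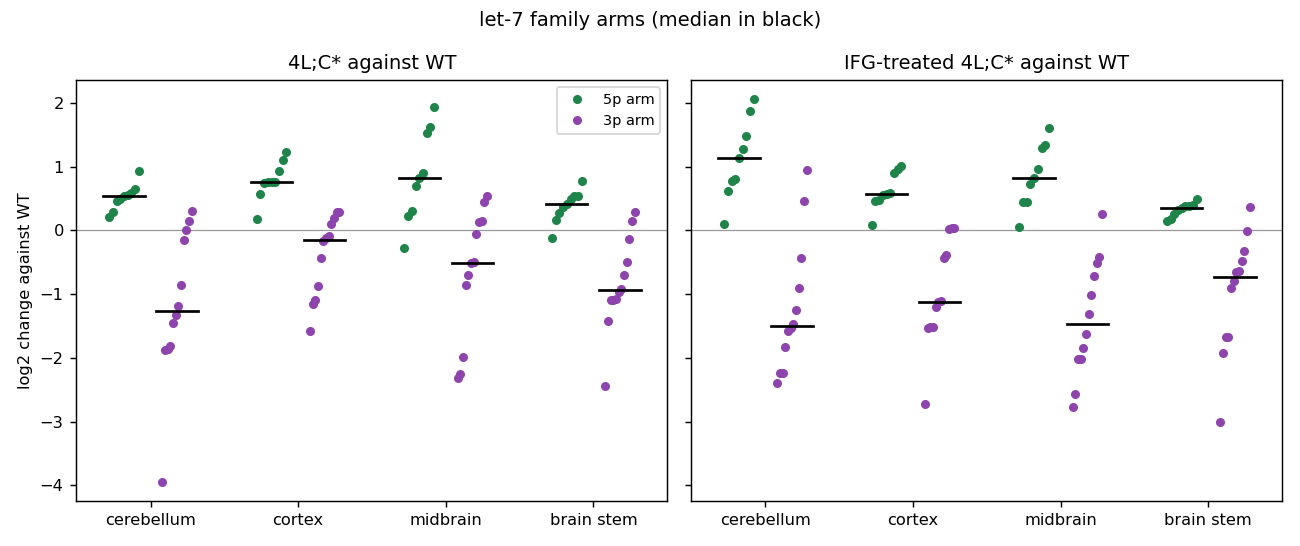
Log2 change against WT of each let-7 family arm, by region, for untreated 4L;C* (left) and IFG-treated 4L;C* (right), with 5p and 3p arms as separate points and their medians in black (n = 3 mice per group, 2 for WT brain stem). In the cerebellum the 5p medians were 0.53 and 1.13 and the 3p medians -1.26 and -1.5.

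Whether treatment moved miRNAs back towards WT was asked across miRNAs within each region. Both changes share the untreated 4L;C* libraries, which alone gives a negative correlation, so correlation and covariance were set against 1000 simulated draws that kept the genotype change and had no treatment change, with miRNAs independent of each other. In the brain stem r was -0.729 across the 614 miRNAs, below every draw (mean -0.251, lowest -0.415). There 96 miRNAs such as miR-34a-5p, miR-301a-3p and miR-1a-3p were lowered by genotype and raised by treatment, but 23 with each library centred on its median and 26 after quantile normalization. In the cortex r was -0.617, below every draw (mean -0.313, lowest -0.454), with 9 such miRNAs, among them miR-218-2-3p and miR-187-5p, and 3 after either scaling. In the midbrain r was -0.553, below every draw (mean -0.239, lowest -0.382), with 37 such miRNAs, and 16 including miR-5117-5p went up then down (30 and 23 after centring, 26 and 27 after quantile normalization). In the cerebellum r was -0.380, inside the draws (mean -0.286, lowest -0.450), while the covariance of -0.163 was below every draw (lowest -0.135), and 18 went down then up. Against draws of groups with no change at all, r was below the lowest in brain stem (-0.590) and cortex (-0.613) and above it in midbrain (-0.613) and cerebellum (-0.615), and the covariance was below the lowest in every region. The shared libraries favour such opposite calls too, and no value without change was simulated for these counts. The slope of the treatment change on the genotype change, less what noise in the shared libraries gives, was -0.671 in brain stem, -0.515 in cortex, -0.378 in midbrain and -0.275 in cerebellum. Leaving out single mice moved the cerebellar slope between -0.444 and 0.0753. The shared untreated group was not split between both changes, and miRNAs are not independent replicates. The genotype and treatment changes correlated with GC content at r = 0.246 and -0.279 in brain stem and -0.138 and 0.110 in cortex. In midbrain these were -0.242 and 0.066, and in cerebellum 0.183 and 0.033. The draws included no trend shared by miRNAs in the untreated libraries. Such a trend was thus not told apart from a reversal, above all in brain stem.

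**Figure D3:**
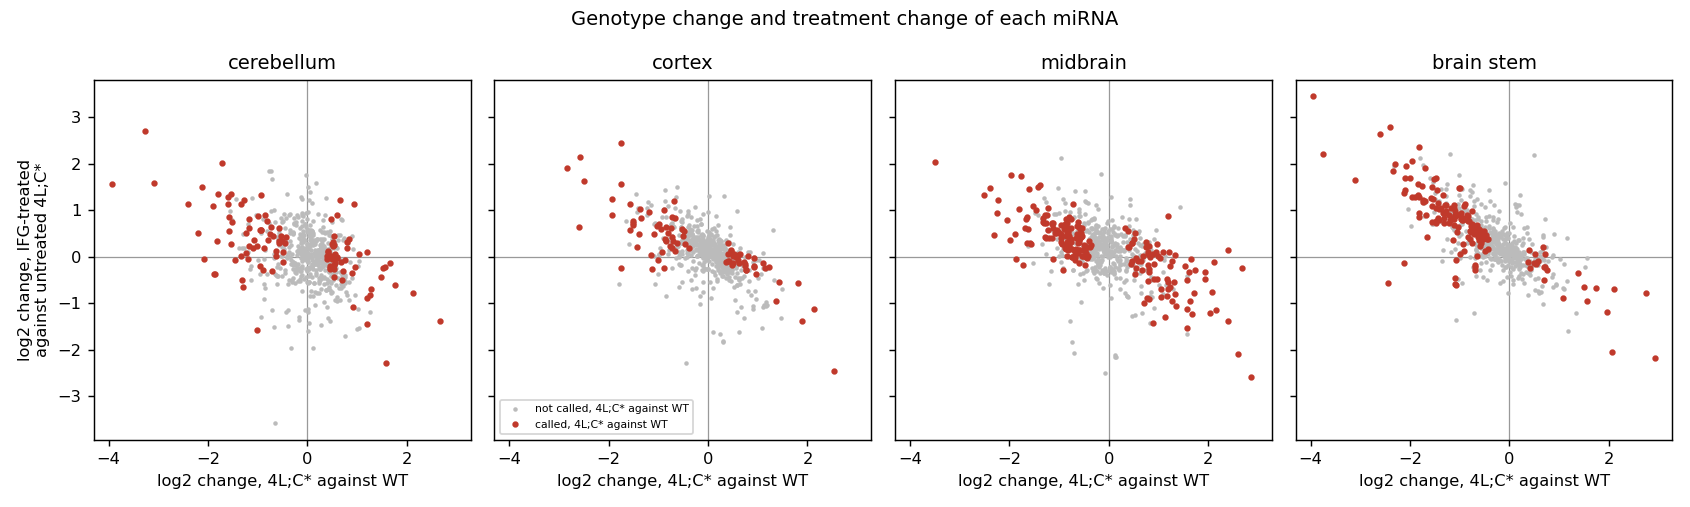
Log2 change of IFG-treated against untreated 4L;C* (y axis) by log2 change of untreated 4L;C* against WT (x axis), a panel per region, each point a miRNA of the 614 tested, in red where called between 4L;C* and WT (n = 3 mice per group, 2 for WT brain stem). The correlation ran from -0.38 in the cerebellum to -0.73 in the brain stem, and draws without a treatment change gave means from -0.239 to -0.313.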

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

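Of the tests in this part, the scaling test of the brain stem pattern and the tests of reads shared between let-7 copies and between all 5p arms were chosen only after the results were seen, as were the let-7 pattern itself, the GC trend removal, the tests on recovered reads, the 8 miRNAs with the smallest p for each difference between regions, and the share of other small RNA classes worth listing. The genotype effect differed between regions for 172 miRNAs and the treatment effect for 66, by limma F tests adjusted by Benjamini-Hochberg. The most different genotype effects, in the order cerebellum, cortex, midbrain and brain stem, were those of let-7i-5p (0.28, 0.92, 1.62 and 0.37, adjusted p = 2.40e-07), miR-30a-5p (-0.07, 0.61, 0.96 and -0.48, adjusted p = 1.04e-06), miR-98-5p (0.47, 1.23, 1.94 and 0.28, adjusted p = 2.18e-06) and miR-383-5p (0.37, 0.15, -1.25 and -0.46, adjusted p = 4.40e-06). MiR-181d-5p (-0.10, 0.01, 0.80 and -0.45), miR-126-5p (-0.64, 0.43, 0.99 and -0.92), miR-342-3p (0.60, 0.36, -0.62 and 0.35) and miR-190-5p (-1.09, 0.79, 2.12 and -1.44) each had adjusted p = 1.16e-05. The most different treatment effects, in the same order, were those of miR-298-5p (-1.96, 0.27, 0.40 and 0.19) and miR-423-5p (-3.58, 0.29, 0.50 and -0.05), each with adjusted p = 1.35e-08, and let-7a-5p (1.23, -0.28, 0.02 and -0.14, adjusted p = 2.29e-07). MiR-134-5p (1.60, 0.01, 0.49 and 0.09) and let-7c-5p (1.13, -0.20, 0.00 and -0.28) each had adjusted p = 2.13e-06, followed by miR-376b-3p (-1.19, 0.58, 0.51 and 0.67, adjusted p = 3.69e-06), miR-98-3p (1.55, -2.29, -2.49 and -0.56, adjusted p = 4.37e-05) and let-7g-5p (0.91, -0.29, 0.07 and 0.27, adjusted p = 0.000163).

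Small RNA classes outside the miRNA comparisons also differed by limma. In the 4L;C* midbrain, 82 of 245 tRNA features, 17 of 54 U RNA features and 5 of 19 other small RNA features were higher than in WT, and in the brain stem 5 of 19 other small RNA features were higher. The WT brain stem library labelled outlier had 82.2% of the tested miRNAs above the floor on 186152 recovered reads, where 1 read was worth 4.31 scaled reads. It correlated with the other WT brain stem libraries at r = 0.890 and 0.876 across miRNAs, against 0.986 between those 2, and had 17.8% of tested miRNAs at the floor against 2.61% and 3.91%.

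The first pattern weighed was that most miRNAs called in the 4L;C* brain stem were lower than in WT (140 of 164, or 85.4%). Loss of low miRNAs to the floor in shallower libraries was argued against, since the 307 miRNAs with a mean above the median had a median change of -0.26. GC content bias was not decided: 86.7% of calls were still lower after removal of the GC trend, but that removal left the median change at -0.37. The removal thus could not test a general shift, and the change correlated with GC content at r = 0.246 across miRNAs. Scaling over all small RNA classes cannot be told apart from a general fall of miRNAs: centring brought the lower share to 54.1%, which centring by itself favours, while the snoRNA and scaRNA features that share the scaling had a median of 0.0719, short of the rise of over 0.2 that the explanation asked for, but the tRNA features that share it too had a median of 0.27 (31 of 245 higher and 7 lower). A genotype effect on miRNA content as a whole stays open and untested, as WT had 2 libraries and the files name no spike-in.

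The second pattern was that let-7 5p arms were higher (median 1.00) and let-7 3p arms lower (median -1.20) in IFG-treated 4L;C* mice than in WT, by means over 3 regions. GC content bias was argued against, since the 5p median was 0.99 after the GC trend was removed. A loss of all passenger arms was argued against, since over 190 other hairpins the less abundant arm moved against the more abundant one by a median of -0.14 (SD 0.53). Reads shared between all 5p arms were argued against, since within a region the arms spanned a range of up to 1.95 (cerebellum, let-7d-5p at 0.11 and let-7c-5p at 2.06), but reads shared between close let-7 copies cannot be told apart from separate changes, as the means spanned 0.92 and let-7a-1-3p and let-7c-2-3p had nearly the same values. Let-7a-1-3p and let-7c-2-3p moved nearly alike in every region (-2.02 and -2.01 in the treated midbrain), so counts of 3p arms may hold the same reads more than once. By means over 3 regions the 3p median was -0.56 in untreated and -1.20 in treated mice. A change in let-7 processing or arm choice with the genotype or the treatment is a candidate explanation that these data do not test.

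The third pattern was the set of changes found with treatment in the cerebellum, with miR-423-5p lower and let-7a-5p and let-7c-5p higher. GC content bias was argued against, since at least 100.5% of each of the 3 changes was left after removal of the GC trend, and scaling by 1 factor per library was argued against, since such a factor moves all miRNAs of a library alike, while miR-423-5p (-3.58) and let-7a-5p (1.23) moved apart around a median of 0.04. Centring shifts all miRNAs by a similarly small amount and so decides nothing by itself (at least 96.9% was left). Quantile normalization, which rescales abundant miRNAs, left miR-423-5p at -3.49 and let-7a-5p at 0.58 (adjusted p = 0.00218), but let-7c-5p went from 1.13 ± 0.13 to 0.48 ± 0.17 and lost its call (adjusted p = 0.0629) because its change fell while its error rose. The treatment effect on each of the 3 differed between regions (adjusted p of 2.13e-06 or lower), and a biological effect of IFG on the cerebellum stays open, with its mechanism untested.

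For the comparisons of 3 libraries with 3, the real split gave the largest count of the 10 splits (1 of 10), but 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 114 and 1 in cerebellum, 83 and 1 in cortex and 201 and 26 in midbrain for 4L;C* against WT. For IFG-treated against untreated 4L;C* they were 93 and 4, 20 and 0, 85 and 57, and 146 and 1 in cerebellum, cortex, midbrain and brain stem, and for IFG-treated 4L;C* against WT 134 and 1, 57 and 0, and 137 and 0 in cerebellum, cortex and midbrain. For the means over 3 regions they were 225, 162 and 158 against 0 in each case, and for the effects differing between regions 172 and 0 for genotype and 66 and 6 for treatment. Of 100 drawn splits of the WT libraries, 1 gave a count as large as the cerebellum (345, highest other 322), 2 as large as the cortex (281, highest other 345) and 2 as large as the midbrain (322, highest other 345). This makes chance unlikely there but does not exclude it. The highest other count, 345, is that of the cerebellum split. The comparisons with the 2 WT brain stem libraries were not given a split test.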

How the results depend on the processing

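Limma voom on recovered reads, all small RNA classes together, the GC trend removal, the settings of the list tests, the slope of the reversal, the scalings and added draws for it, and the scalings of calls shared between regions were chosen only after the data were seen, and the other alternatives were planned. Over the counts, list calls and correlations, 315 values under an alternative stayed within 1.5 times of the reported one and 49 did not. No list call reversed its direction under any alternative run.

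With the 2 compared groups fitted alone, the counts became 71 (cerebellum) and 106 (brain stem) for 4L;C* against WT, 48 (cerebellum), 13 (cortex) and 4 (midbrain) for IFG-treated against untreated 4L;C*, and 137 (cortex) and 63 (brain stem) for IFG-treated 4L;C* against WT. Fewer libraries then estimate the spread. With each library centred on its median, the counts became 109 for 4L;C* against WT in brain stem, 76 for treatment in brain stem (84 after quantile normalization) and 34 for IFG-treated 4L;C* against WT in cortex (34 after quantile normalization). Both move the shifted medians to a common level by construction. Without the brain stem, 41 treatment effects differed between regions. List calls numbered 28, but 1 with an estimated correlation and 14 with the stricter filter, which leaves fewer members. The reversal correlation in cerebellum was -0.22 over miRNAs with a mean above the median, where the cause was not tested.

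Values of named miRNAs that changed sign had the following values, and the cause was not tested. After centring, miR-127-3p was at -0.00678 for treatment in brain stem. After quantile normalization, miR-128-3p was at -0.142 and miR-486-5p at -0.0407 for IFG-treated 4L;C* against WT in cerebellum, miR-434-3p at -0.0190 for the same in cortex, miR-486-5p at -0.0784 for treatment in the mean of 3 regions, and miR-181b-5p at 0.0746 for the WT midbrain. With all 35 libraries in the region contrasts, miR-150-5p was at 0.0694, miR-21-5p at -0.0906 and miR-126-5p at -0.0259 in cerebellum, miR-9-3p at 0.0804 in cortex, miR-138-5p at 0.238, miR-29b-1-5p at -0.0185 and miR-127-5p at 0.20 in midbrain, and miR-30e-5p at -0.0549 in brain stem. Named values include list members that had not passed, so a value that stayed the same need not have had a call. Of those each alternative applies to, 958 stayed the same and 152 were weaker after quantile normalization, and 1009 and 105 after centring. The numbers were 1052 and 40 after removal of the GC trend, 452 and 146 with the 2 groups alone, and 1014 and 59 with voom. Over fits without 1 mouse, 4676 stayed the same, 974 were weaker and 0 reversed. The fold of 50 of the 1115 values moved by over 1.5 times, at most 2.34 times.

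Leaving out 1 mouse gave these ranges of counts. For 4L;C* against WT they were 47 to 130 in cerebellum, 54 to 78 in cortex, 176 to 218 in midbrain, 73 to 164 in brain stem and 178 to 215 in the mean of 3 regions. For IFG-treated against untreated 4L;C* they were 53 to 96, 5 to 20, 23 to 150, 68 to 160 and 103 to 159 in the same order, and for IFG-treated 4L;C* against WT 102 to 126, 29 to 51, 102 to 135, 9 to 18 and 126 to 149. For WT regions they were 294 to 305 (cerebellum), 212 to 235 (cortex), 269 to 276 (midbrain) and 163 to 273 (brain stem). Effects differing between regions numbered 114 to 188 for genotype and 39 to 91 for treatment, and list calls 15 to 29, the lowest without 4L;C* mouse 5186. The reversal correlation ran from -0.54 to -0.28 in cerebellum (-0.54 without mouse 5186, -0.28 without 5187), -0.69 to -0.58 in cortex, -0.66 to -0.50 in midbrain and -0.77 to -0.66 in brain stem. Where a WT brain stem library was left out, the lone library was assumed to vary like the other groups.

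With mouse as a replicate block the counts were 233, 167 and 170 for the means of 3 regions, 337, 280, 315 and 272 for the WT cerebellum, cortex, midbrain and brain stem, and 166 and 63 for effects that differ by region. Across miRNAs, residuals of regions of the same mouse had a mean r of -0.04 in 4L;C*, 0.04 in IFG-treated 4L;C* and -0.0008 in WT, against 0.02, -0.02 and 0.0004 for regions of different mice. Residuals cancel within a group, so the values for different mice follow from those for the same mouse and are no separate comparison. Pseudocounts and count models as planned for linear values or counts were not run, since the deposited values are on a log2 scale. Depth limits low miRNAs: up to 9.61% of those tested lay at the floor in a grouped library.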

Other observations

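The tests of other small RNA classes, the counts of shared and opposite calls and the view of single mice were chosen only after the results were seen. Small RNA of other classes moved with genotype by limma. In the 4L;C* midbrain, tRNA features had a median change of 0.77 against WT and U RNA features 0.64, while of 297 snoRNA and scaRNA features 98 were lower and 38 higher (median -0.29). With treatment in the midbrain, 47 snoRNA and scaRNA features were higher and 5 lower (median 0.14), in a comparison that shares the untreated libraries, which favours the opposite direction. In the IFG-treated cerebellum, 42 of 245 tRNA features were lower than in WT and 4 higher (median -0.49), and 30 of 297 snoRNA and scaRNA features were higher and 9 lower.

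MiR-5117-5p, higher in untreated 4L;C* than WT in every region, stayed high in 1 of the IFG-treated mice in all 4 regions. In mouse 5755 its level was 6.70 log2 scaled reads in brain stem, 6.97 in cerebellum, 6.22 in cortex and 7.13 in midbrain, against 4.79 to 5.07, 5.29 to 5.33, 3.73 to 3.9 and 4.65 to 5.43 in the other treated mice. These levels rest on 167, 92, 74 and 144 reads in mouse 5755.

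MiRNAs that went up with genotype and down with treatment numbered 5 in cerebellum, 2 in cortex, 16 in midbrain and 5 in brain stem, then 6, 3, 23 and 19 with each library centred on its median and 8, 4, 27 and 26 after quantile normalization. Both comparisons use the untreated libraries, which favours such opposite calls, so these counts test no reversal. The covariance of both changes was -0.163, -0.204, -0.273 and -0.368 in these regions, against a lowest of -0.135, -0.128, -0.134 and -0.140 in draws that kept the genotype change and had no treatment change. Those draws took miRNAs as independent, so they do not cover a trend shared by miRNAs in the untreated libraries. Over at least 3 regions, genotype raised 14 miRNAs and lowered 29, and treatment raised 11 and lowered 3 (miR-9-3p, let-7f-1-3p and miR-5117-5p). These were counted with the deposited scaling only, which weighs on their balance of rises and falls. In brain stem, centring took genotype calls from 24 higher and 140 lower to 50 and 59. It took treatment calls there from 137 higher and 9 lower to 35 and 41. For genotype, cortex and midbrain shared 23 rises where 4.45 were expected by chance, and midbrain and brain stem 35 falls where 28 were expected (13 against 10.7 after centring, 11 against 8.44 after quantile normalization).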
